A study of Homo sapiens with 2 samples.

How the data were processed

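RNA from HCT116 cells, an established human colon cancer line, was compared on 2 two-colour oligonucleotide arrays (Agilent whole-genome design). Per the labels, each array carried RNA from cells transduced with a lentiviral short hairpin RNA (shRNA) against the long non-coding RNA FLANC in the Cy3 (green) channel. The Cy5 (red) channel held RNA from cells with a control vector, which the titles call an empty vector. The titles number the arrays as biological replicates 1 and 2, whereas both free-text descriptions say replicate 2, and the numbers of the titles were used. Both arrays formed 1 group. Both lay on the same slide and were scanned together, so no slide or scan batch could be separated from anything else.

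Per the file headers, the deposited scanner files hold spot intensity values (median pixel brightness of each spot and of its local background, not yet normalized) written by Agilent Feature Extraction 10.7.3.1. The submitters' processing notes name version 8.5.1.1 of the same software. The genome build of the probe design was hg18, per the file headers, and no coordinates are given here. The deposited table of the whole series holds log10 ratios of red over green. Set against the scanner files, its values equalled the scanner software's own log10 ratio within 1e-06 for 43376 of 43376 spots on each array, with a median of 0 in both columns. By the dyes in the labels these ratios are control over FLANC shRNA, although the column titles name the FLANC shRNA first, so reading the deposited table as FLANC shRNA over control would turn every sign. The software had set the log10 ratio to 0 for 6777 spots of array 1 and 6536 of array 2, none of them well above background in both channels. No further step by the authors was given in the sources used here.

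Each array had 45015 spots, of which 43376 were not controls, for 41000 different probes. Signals were corrected for background with limma 3.58.1 in R 4.3.3 (normexp, offset 50, on the median spot signal and the median local background). The fixed plan named the mean spot signal, but the files hold medians, which were used instead. The log ratios were normalized within each array by loess, with control spots and spots flagged as outliers (129 on array 1 and 145 on array 2) at weight 0. No spot was flagged as saturated. Every ratio was then turned to FLANC shRNA over control. Spots of one probe were averaged, and where several probes measured a gene the probe with the highest mean log2 intensity was kept. A gene was tested when it was well above background, by the scanner software's flag, in the same channel on both arrays. The accession of each probe was matched, without version, to a RefSeq gene table of assembly GRCh38.p14, used for names only. Of the 41000 probes 23958 matched, for 16557 symbols. The 8872 tested features without a match kept the name in the file and are only counted here.

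Genes were tested with limma (lmFit with an intercept and eBayes, two-sided, n = 2 arrays, 1 residual degree of freedom before moderation), with Benjamini-Hochberg adjustment and a threshold of 0.05. The control RNA shared each array with the knock-down RNA, so the ratio was tested against 0, which leaves out the control's own spread as a separate term. A difference of the control channel between the arrays (SD over genes 0.268) is part of the spread of the ratios. This SD was larger within some gene lists described below: 0.908 for ATF4 targets, 0.915 for MAPK feedback genes and 0.557 for STAT3 targets. In the FLANC shRNA channel it was 0.747, 0.970 and 0.672 for these lists, and 0.439 over all genes. Other lists had a smaller control SD, such as 0.167 for cytosolic ribosomal proteins. Nothing in the labels says whether the control RNA of the 2 arrays came from separate cultures. The limma p-values rest on the spread between these 2 arrays and, through moderation, on the variance of all genes (3.48 prior degrees of freedom). They cover no spread beyond these arrays. As the dyes were not swapped, a dye effect that is specific to a probe cannot be separated from the effect of the shRNA. Genes with a ratio of at least 2-fold in the same direction on both arrays were counted as a description, without a test.

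Before the data were examined, 28 gene lists were fixed from textbook knowledge. The 27 lists with at least 5 tested members were tested with limma's camera (preset correlation 0.01, two-sided, adjusted over the lists). With that preset the genes of a list count as nearly independent units, so a small camera p-value does not measure agreement between the arrays. Camera with an estimated correlation and the rotation test fry were run beside it. With 2 arrays the estimated correlation rests on 1 residual degree of freedom. The genes named in the text were chosen by a rule fixed beforehand: the 12 highest and 12 lowest genes that pass the threshold, filled up, where fewer pass, with the genes whose smaller ratio of the 2 arrays was largest. STAT3, VEGFA and up to 4 members of each list with the smallest p were added. Further genes are named in a few places and marked as chosen after their values were seen.

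Alternatives fixed beforehand were no background subtraction, plain subtraction, a normexp offset of 16, median centring, the scanner software's own ratio, the deposited table, Aquantile normalization between arrays, 2 other filters on dim probes, the mean of probes, every probe by itself, leaving out saturated spots, eBayes with trend and robust (statmod 1.5.0), a threshold of 0.1, a 1.5-fold criterion and leaving out either array. For eBayes with trend and robust, the lists were tested by camera's test on the moderated statistics of that fit.

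The steps from spot signals to calls were tested on simulated data, with the brightness and gene variances of these arrays and 21630 genes. Each gene had the same variance on both simulated arrays, and the noise was drawn independently for each gene. Of 67 genes changed 2-fold the limma test called 2.99%, of 67 changed 4-fold 82.1%, and of 66 changed 8-fold 97.0%, and it called 9 of 21391 unchanged genes. Among the unchanged genes 16 were at least 2-fold higher and 28 at least 2-fold lower on both arrays. Camera with the preset correlation called 2 of 2 lists shifted 2-fold and 2 of 25 unshifted lists. Camera with an estimated correlation and fry called 0 of the 2 shifted lists.

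Some steps were changed after a result had been seen. The list test for eBayes with trend and robust was at first camera with its own variance trend, which lost the p53, unfolded protein response and Wnt lists. It was replaced because that trend runs on the mean log ratio and not on brightness, and its counts are given beside the others. A test for a common compression of array 2, at first run on the cholesterol genes alone, was replaced by a permutation between all passing lists, since the cholesterol list had been picked for standing out. It was later run for each common factor from 0 to 1.5 in steps of 0.05, since the factor taken from the SDs of the arrays holds noise too. The dye curve of the simulated data was made smoother after a steeper curve gave more false calls, so the false calls reported for the simulation are on the low side. The rule for spike-in probes above background asked at first for both channels, which no probe met, and was loosened to either channel.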

Results

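The effect of silencing FLANC, a primate-specific long non-coding RNA, on the transcriptome of HCT116 colon cancer cells was measured on 2 two-colour arrays. Each array set cells with a FLANC shRNA (Cy3) against cells with an empty control vector (Cy5). On array 1, 68.4% of the spots that are not controls were well above background in the FLANC shRNA channel and 68.2% in the control channel. The shares on array 2 were 70.0% and 68.0%. After filtering, 21630 genes were tested, 12758 of them with a current symbol. The number of arrays, 2, limits the precision of every ratio. Ratios are given as log2 of FLANC shRNA over control, as mean ± SD over the 2 arrays (n = 2), and fold changes are derived from the mean.

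The target of the shRNA was looked for first. No probe on the array was named FLANC (0 of 41000 probes), and the name table did not list it, so the knock-down itself was not measured under that name. The direction of every ratio therefore rests on the dyes given in the labels. The adenovirus E1A spike-in probes lay close to background, with median background-subtracted signals of 2.07 and 2.56 in the FLANC shRNA channel and 1.27 and 2.01 in the control channel of arrays 1 and 2. The median over all spots that are not controls was 68.7 and 72.3 in the FLANC shRNA channel and 81.9 and 78.0 in the control channel.

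The comparison asked which transcripts differed between FLANC shRNA and control cells. Genes of the amino acid and ATF4 stress response were lower in FLANC shRNA cells on both arrays, and so, as groups, were feedback and immediate early genes of MAPK signalling, cytosolic ribosomal proteins and a set of epithelial junction genes. Genes of cholesterol synthesis, DNA replication, heat shock, oxidative phosphorylation, p53 and Wnt targets were higher as groups. In total, 12 of the 27 gene lists tested passed camera with its preset correlation, 6 in each direction, and 0 passed with an estimated correlation (smallest p = 0.0875, smallest adjusted p = 0.798). That version rests on 1 residual degree of freedom, and in simulated data it called 0 of 2 lists shifted 2-fold. Its adjusted p of 0.798 therefore cannot tell whether correlation between genes explains a call. With a variance trend added to camera 9 lists passed, without the p53, unfolded protein response and Wnt lists (adjusted p = 0.126, 0.0749 and 0.319). On simulated data the preset correlation also called 2 of 25 unshifted lists. The simulated noise was independent between genes, so this count cannot give the rate of false calls for lists of correlated genes. The estimated correlation was 1 for ribosomal proteins, 0.75 for heat shock and 0.35 for the ATF4 list, but -0.01 for cholesterol synthesis. By fry 1 list passed, the Wnt targets, and 8 had an unadjusted p under 0.05. No single gene passed the limma test after adjustment (0 of 21630, smallest adjusted p = 0.334), while 2837 genes had an unadjusted p under 0.05, 1225 of them higher and 1612 lower, where 1082 would arise by chance. With plain background subtraction 27 genes passed (1 higher, 26 lower), and with eBayes with trend and robust 26 passed (1 higher, 25 lower), with 19 genes in both sets.

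By the dyes in the labels, the counts by size leaned to lower ratios. On both arrays 102 genes were at least 2-fold lower in FLANC shRNA cells and 10 at least 2-fold higher, where 5.57 and 0.514 would arise if the arrays were unrelated. Simulated arrays gave 28 lower and 16 higher among unchanged genes. The simulation gave both arrays the same spread, whereas the real ratios had an SD over genes of 0.523 on array 1 and 0.297 on array 2. Its counts therefore cannot tell how many of the observed genes would arise by chance. The higher genes made up 8.93% of the measured genes at least 2-fold changed on both arrays. With the scanner software's own ratios the counts were 252 lower and 79 higher, or 23.9% higher. With the dyes exchanged these shares would be 91.1% and 76.1%. Array 1 alone gave 842 lower and 483 higher genes, and array 2 alone 143 and 23.

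**Figure D1:**
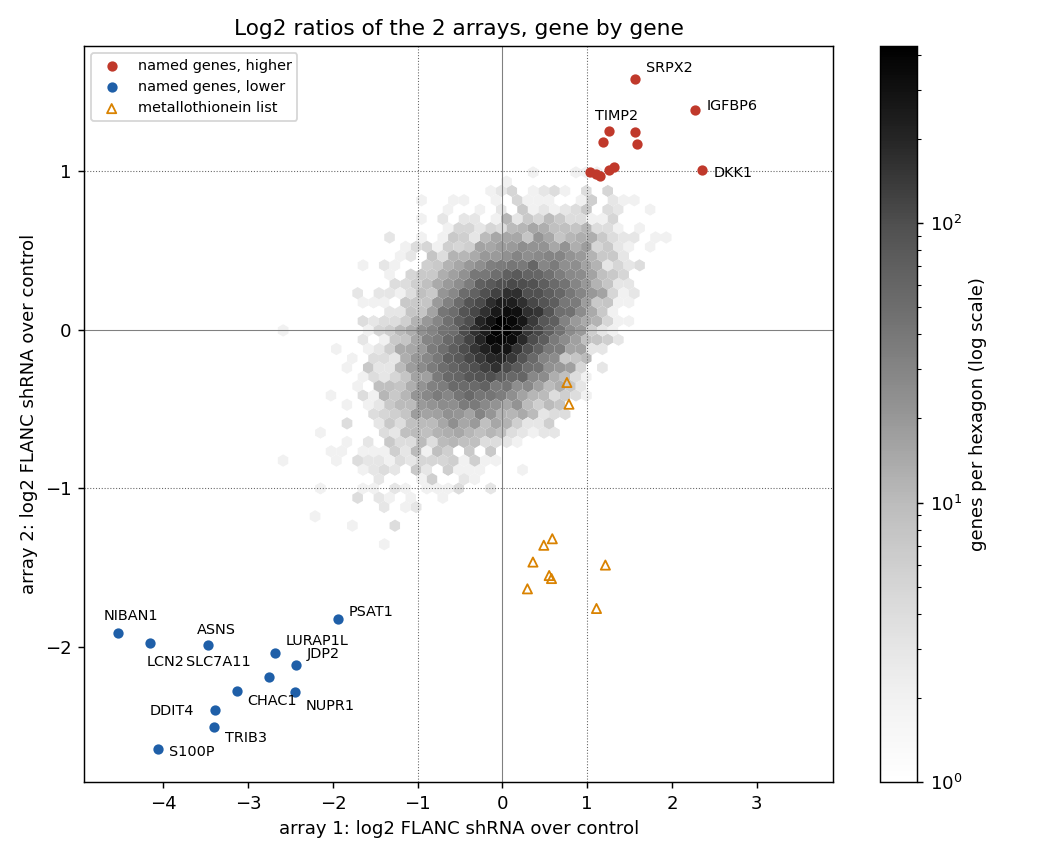
Log2 ratios of FLANC shRNA over control on array 1 (horizontal axis) and array 2 (vertical axis) for the 21630 genes tested. Grey hexagons give the number of genes on a log scale, red and blue points are the 12 higher and 12 lower genes named by the fixed rule, open triangles are the 10 genes of the metallothionein list, and dotted lines mark a ratio of 2-fold. The 12 lower genes lie below the 2-fold lines on both arrays, and the metallothionein list is above 0 on array 1 and below 0 on array 2.

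The ATF4 list had the mean over both arrays furthest from 0. All 21 of its measured genes were lower on both arrays, with medians of -1.67 on array 1 and -1.42 on array 2 (mean over genes -1.76, SD over genes 0.71; camera adjusted p = 5.36e-24). With an estimated correlation the adjusted p = 0.798. Among the members with the smallest p, TRIB3, a stress-induced pseudokinase, was 7.75-fold lower (-2.95 ± 0.63) and CHAC1, a glutathione-degrading enzyme, 6.54-fold lower (-2.71 ± 0.61). The cystine transporter gene SLC7A11 was 5.55-fold lower by its brightest probe (-2.47 ± 0.40) and at -1.58 by the mean of its probes, and PSAT1 of serine synthesis 3.69-fold lower (-1.88 ± 0.08). Further members among the lowest genes of the array were DDIT4, an inhibitor of mTORC1 (-2.90 ± 0.70), and asparagine synthetase ASNS (-2.73 ± 1.05). No member passed the limma test over all genes, and 21 of 21 passed when adjusted over the list alone, all lower. Between the arrays, the control channel of these genes differed with an SD over genes of 0.908, against 0.268 over all genes.

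Other named genes with low ratios included NUPR1, a stress-induced chromatin regulator (-2.37 ± 0.11), and JDP2, a repressor of the AP-1 family (-2.28 ± 0.23). The calcium-binding protein gene S100P was 10.2-fold lower (-3.35 ± 1.00), the iron-siderophore carrier LCN2 8.38-fold lower (-3.07 ± 1.54), NIBAN1 9.33-fold lower (-3.22 ± 1.85) and LURAP1L 5.14-fold lower (-2.36 ± 0.46). Each of the 24 named genes had a limma adjusted p of 0.334. A second probe of NIBAN1 read -0.73, and the mean of its probes was -1.98. Of the 12 lower genes named by the rule, S100P, TRIB3, DDIT4, NUPR1, CHAC1, SLC7A11, JDP2 and LURAP1L passed under both plain subtraction and eBayes with trend and robust, and PSAT1 under the latter.

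The unfolded protein response list was lower as a group (camera adjusted p = 0.0327), with medians of -0.42 and -0.13, and its members went both ways. The adjusted p = 0.798 with an estimated correlation. Of 17 genes, 10 were lower and 4 higher on both arrays. The membrane protein HERPUD1 (-1.53 ± 0.43), the degradation adaptor SEL1L (-1.17 ± 0.34) and the co-chaperone DNAJB9 (-1.57 ± 0.70) were low, and SDF2L1, also of the endoplasmic reticulum, was high (0.85 ± 0.07). No member passed over all genes, and 6 lower and 3 higher members passed when adjusted over the list alone.

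VEGFA, the main angiogenic growth factor, was 4.52-fold lower by its brightest probe (-2.18 ± 0.68, limma adjusted p = 0.334) and at -1.18 by the mean of its probes. STAT3 itself was at 0.52 on array 1 and 0.09 on array 2 (0.30 ± 0.30, limma adjusted p = 0.531). The list of STAT3 targets was lower as a group (camera adjusted p = 0.0210), with medians of -0.26 and -0.13, and 11 of its 24 genes were lower and 5 higher on both arrays. With an estimated correlation the adjusted p = 0.798, and with the scanner software's ratios the preset test gave 0.070. Besides VEGFA, the transcription factors CEBPD (-1.25 ± 0.02) and CEBPB (-1.71 ± 0.74, with a second probe at -0.33) were low, the latter also a member of the ATF4 list, while HSPA1A was high (1.41 ± 0.23). Over all genes 0 members passed, and 4 lower and 1 higher member passed when adjusted over the list alone. The hypoxia and angiogenesis list did not pass (camera adjusted p = 0.198), with 11 of 24 genes lower and 3 higher on both arrays, among them NDRG1 (-1.20 ± 0.61), PDK1 (-0.68 ± 0.07) and ANKRD37 (-0.60 ± 0.22).

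The list of MAPK feedback and immediate early genes had medians of -0.88 and -0.50, with 16 of 22 genes lower and 0 higher on both arrays (camera adjusted p = 1.89e-08). Camera with an estimated correlation gave an adjusted p of 0.798. The epidermal growth factor receptor ligands HBEGF (-1.15 ± 0.33) and AREG (-1.05 ± 0.25) and the early response genes IER3 (-1.39 ± 0.48) and PHLDA1 (-1.12 ± 0.27) had the smallest p. None of the members passed over all genes, and 11 passed when adjusted over the list alone, all lower. The list of epithelial junctions and keratins was lower as a group too (medians -0.62 and -0.18, camera adjusted p = 0.00991; with an estimated correlation the adjusted p = 0.798). The splicing factor ESRP1 (-1.28 ± 0.19), the claudin CLDN7 (-0.72 ± 0.21), occludin OCLN (-0.87 ± 0.44) and TJP1 (-0.97 ± 0.65) were low, 9 of 17 genes were lower and 4 higher on both arrays, and 1 lower member passed when adjusted over the list alone and 0 over all genes.

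Cytosolic ribosomal protein genes were lower by a small and even amount, with medians of -0.76 and -0.25, and 26 of 30 were lower and 0 higher on both arrays (mean over genes -0.49, or -0.22 with the scanner software's ratios; camera adjusted p = 6.65e-10). With an estimated correlation, which called 0 of 2 shifted lists in simulated data, the adjusted p = 0.798. RPS14 (-0.66 ± 0.23), RPL10A (-0.67 ± 0.26) and RPL8 (-0.66 ± 0.31) were among the members with the smallest p, and 0 members passed over all genes or adjusted over the list alone. Subunits of oxidative phosphorylation were higher as a group, with medians of 0.50 and 0.20, and 22 of 27 were higher and 1 lower on both arrays (camera adjusted p = 1.09e-06). With an estimated correlation the adjusted p = 0.798. The members SDHA (0.89 ± 0.16) and SDHB (0.59 ± 0.34) of complex II and NDUFA2 (0.66 ± 0.17) and NDUFB3 (0.88 ± 0.54) of complex I had the smallest p, and 0 passed over all genes or adjusted over the list alone.

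**Figure D2:**
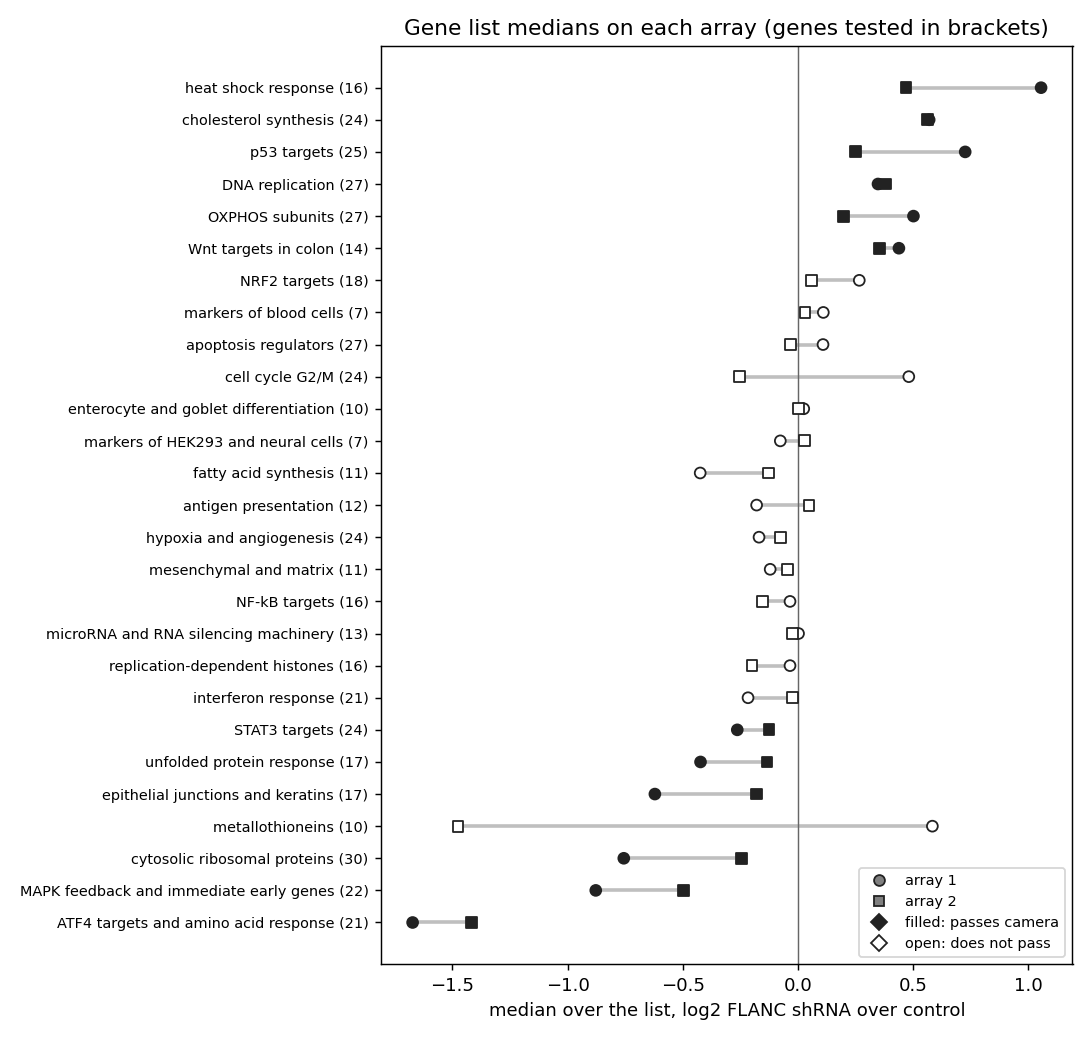
Median log2 ratio of FLANC shRNA over control (horizontal axis) of each of the 27 gene lists tested (vertical axis, genes tested in brackets) on array 1 (circles) and array 2 (squares). Filled symbols mark the 12 lists that passed camera with the preset correlation. The ATF4 list lies lowest on array 1 at -1.67, and the metallothionein list has medians of 0.58 and -1.48.

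Cholesterol synthesis was the list with the most even ratios across the arrays among those that were higher, with medians of 0.57 and 0.56 (camera adjusted p = 6.65e-10; with an estimated correlation the adjusted p = 0.798). Of 24 genes, 19 were higher and 2 lower on both arrays. Squalene synthase FDFT1 (1.03 ± 0.21), the sterol sensor INSIG1 (0.98 ± 0.17) and isopentenyl diphosphate isomerase IDI1 (0.91 ± 0.06) were among the members with the smallest p. No member passed over all genes, and 12 passed when adjusted over the list alone, all higher. The fatty acid synthesis list did not pass (camera adjusted p = 0.402), with the synthase FASN high (0.73 ± 0.23) and the regulator SREBF1 (-0.92 ± 0.74), ACSL3 (-0.67 ± 0.32) and ACSS2 (-0.55 ± 0.26) low.

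DNA replication genes were higher as a group, with medians of 0.35 and 0.38, and 22 of 27 were higher and 0 lower on both arrays (camera adjusted p = 6.65e-10). The adjusted p = 0.798 with an estimated correlation. The flap endonuclease FEN1 was 2.27-fold higher on each array (1.18), the sliding clamp PCNA 2.12-fold (1.09 ± 0.35), RRM1 of nucleotide reduction 1.75-fold (0.81 ± 0.23) and the helicase subunit MCM4 1.64-fold (0.72 ± 0.16). Over all genes 0 members passed, and 2 passed when adjusted over the list alone. The G2/M list did not pass (camera adjusted p = 0.402), with medians of 0.48 on array 1 and -0.25 on array 2, and 14 of its 24 genes had opposite signs on the arrays. Whether the G2/M list differed from DNA replication was not tested. BUB1B (0.72 ± 0.60) and CDK1 (0.55 ± 0.58) were high and NDC80 (-0.58 ± 0.41) and CDC25C (-0.37 ± 0.25) low. Replication-dependent histones did not pass (camera adjusted p = 0.326), with H4C3 (-0.65 ± 0.06) and H4C8 (-0.60 ± 0.05) low, H3C4 at -0.35 ± 0.43 and H2BC12 at 0.34 ± 0.34.

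The list of p53 targets was higher as a group, with medians of 0.73 and 0.25 (camera adjusted p = 0.00209), but its members went both ways. Camera with an estimated correlation gave an adjusted p of 0.798. Of 25 genes, 17 were higher and 5 lower on both arrays. Of the 4 members with the smallest p, TP53INP1 was high (1.05 ± 0.22), and the stress sensor SESN2 (-1.54 ± 0.03), which is also in the ATF4 list, the death receptor TNFRSF10B (-1.28 ± 0.19) and the growth arrest gene GADD45A (-0.97 ± 0.16) were low. None of the members passed over all genes, and 8 higher and 3 lower passed when adjusted over the list alone. Apoptosis regulators did not pass (camera adjusted p = 0.402), with BIRC3 (0.71 ± 0.36), BAD (0.62 ± 0.28) and the death receptor FAS (1.27 ± 1.08) high beside the low TNFRSF10B.

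Heat shock genes had medians of 1.06 and 0.47, and 15 of 16 were higher and 0 lower on both arrays (camera adjusted p = 1.72e-10). With an estimated correlation, which called 0 of 2 shifted lists in simulated data, the adjusted p = 0.798. HSPA1A was 2.66-fold higher (1.41 ± 0.23), HSPA4L 2.92-fold (1.55 ± 0.83), the constitutive chaperone HSPA8 2.20-fold (1.14 ± 0.57) and HSPB1 1.57-fold (0.65 ± 0.15). HSPA1A and HSPA1B are nearly identical, so the value of HSPA1A can include its copy. No member passed over all genes, and 9 passed when adjusted over the list alone, all higher.

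Wnt targets were higher as a group (medians 0.44 and 0.36, camera adjusted p = 0.00209, fry adjusted p = 0.0295). With an estimated correlation the camera adjusted p = 0.798. Of 14 genes, 7 were higher and 2 lower on both arrays. The feedback inhibitor AXIN2 was 2.61-fold higher (1.38 ± 0.30), the secreted Wnt antagonist DKK1 3.21-fold (1.68 ± 0.96), the transcription factor SP5 2.84-fold (1.51 ± 0.83) and BMP4 1.79-fold (0.84 ± 0.10). AXIN2 and DKK1 are inhibitors of the pathway, and the targets MYC and CCND1, chosen after their values were seen, were at -0.02 ± 0.04 and -0.33 ± 0.41. Over all genes 0 members passed, and 6 passed when adjusted over the list alone, all higher.

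Other named genes with high ratios were the secreted proteins SRPX2 (1.57 ± 0.01, 2.97-fold), IGFBP6, which binds insulin-like growth factors (1.83 ± 0.63, 3.55-fold), and the metalloproteinase inhibitor TIMP2 (1.26 ± 0.003, 2.39-fold). The retinoic acid carrier CRABP2 (1.14 ± 0.18), the kinase gene SGK1 (1.04 ± 0.09), the nuclear receptor gene NR2F2 (1.06 ± 0.13), the RNA-binding protein gene NANOS1 (1.01 ± 0.03, or 1.67 with the scanner software's ratio) and the glutamate receptor subunit GRIN2C (1.17 ± 0.21) followed. A second probe of GRIN2C read 0.19, and the mean of its probes was 0.68. Only SRPX2 among the 12 higher genes named by the rule passed under plain subtraction and under eBayes with trend and robust.

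**Figure D3:**
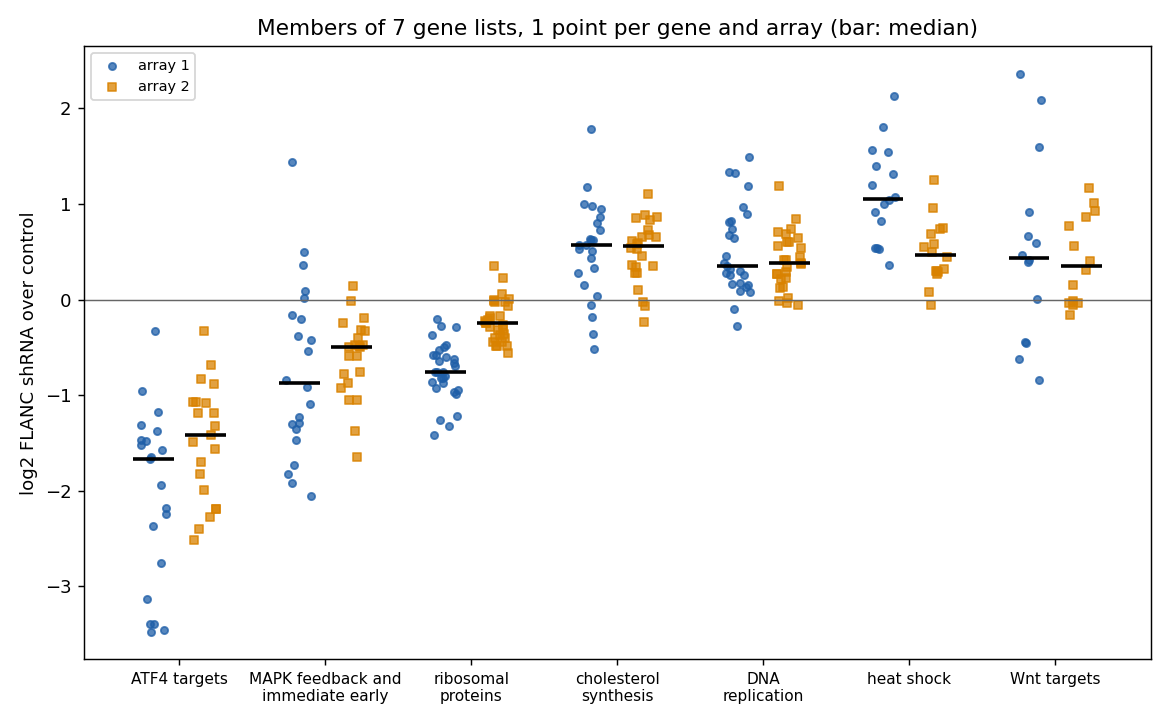
Log2 ratio of FLANC shRNA over control (vertical axis) of every tested member of 7 gene lists (horizontal axis) on array 1 (blue circles) and array 2 (orange squares), with bars at the medians. All 21 ATF4 genes lie below 0 on both arrays, and the heat shock medians are 1.06 and 0.47.

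The metallothionein list, zinc-binding proteins with the zinc exporter SLC30A1, had a median of 0.58 on array 1 and -1.48 on array 2, and all 10 genes had opposite signs on the arrays (camera adjusted p = 0.402). The values of MT2A were 0.30 and -1.64, those of MT1G 0.36 and -1.47, of MT1A 0.55 and -1.55, and of MT1X 0.49 and -1.36. Metallothionein genes are nearly identical in sequence, so the probes may share signal.

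The remaining lists did not pass camera. Interferon response genes had an adjusted p of 0.198, with IRF9 (-0.93 ± 0.45), ISG20 (-0.99 ± 0.56), IFITM1 (-1.13 ± 1.03) and IRF7 (-0.51 ± 0.41) low. NF-kB targets had 0.206, with the chemokine genes CXCL2 (-1.52 ± 0.13) and CXCL1 (-0.75 ± 0.30) low and BIRC3 high. Antigen presentation had 0.821, with PSMB10 (0.85 ± 0.61) and TAP1 (0.55 ± 0.30) high and HLA-B (-0.53 ± 0.55) and HLA-F (-0.50 ± 0.69) low. NRF2 targets had 0.662, with a mean of -0.07, a median of 0.25 and a test direction upward, and GCLC (-0.71 ± 0.25) and SRXN1 (-1.20 ± 0.79) joined SLC7A11 among the low members while ABCC2 was high (0.54 ± 0.36). Mesenchymal and matrix genes had 0.608, with ITGA5 (-0.59 ± 0.06), CCN1 (-0.37 ± 0.02) and CCN2 (-0.29 ± 0.24) low and SNAI1 (0.49 ± 0.01) high. Enterocyte and goblet differentiation had 0.555, with CA2 at 0.51 ± 0.34, CEACAM1 at 0.75 ± 0.99, MUC2 at -0.16 ± 0.04 and CA1 at 0.15 ± 0.25. The microRNA machinery had 0.662, with TARBP2 at 0.34 ± 0.09, AGO3 at -0.28 ± 0.01, TNRC6A at 0.27 ± 0.23 and AGO1 at -0.23 ± 0.08. Markers of blood cells had 0.322, with 7 of 17 genes tested, and markers of HEK293 and neural cells 0.821, with 7 of 15 tested, a mean of 0.05, a median of -0.003 and a test direction upward. HBA1 (0.52 ± 0.26), CD68 (0.31 ± 0.004), CD8A (-0.27 ± 0.19) and HBA2 (0.21 ± 0.28) led the former, and TUBB3 (0.69 ± 0.61), MAP2 (-0.40 ± 0.30), ENO2 (0.13 ± 0.38) and INA (-0.05 ± 0.06) the latter. The list of fibroblast and endothelial markers had 3 tested members and was not tested.

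Across genes, the log2 ratios of the 2 arrays had a Pearson r of 0.458 and a Spearman rho of 0.376, and genes are not independent replicates. The same sign was seen for 62.2% of genes (95% exact binomial interval 61.5 to 62.8, which treats genes as independent). Ratios spread more widely on array 1 (SD over genes 0.523) than on array 2 (0.297). Of 4258 named genes with several probes, the brightest and the second probe had the same sign in 74.8%, with r = 0.727. Among the 24 genes named by the rule, 0 of the 8 with several probes had a second probe of opposite sign.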

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

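The comparison of replicate spots was planned before its result was seen, and the other tests in this part were chosen after the patterns were seen, and the compression test, the reading of SLC30A1 and the rule for the spike-in probes were also revised after a result had been seen.

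A signal appeared in data that no comparison used. One of the 10 E1A spike-in probes was well above background in the FLANC shRNA channel at 32 of 32 spots on both arrays, with a median background-subtracted signal of 22.6, whereas the spots of negative controls were above background in 3 of 612 readings. In the control channel it passed at 22 and 25 of 32 spots, and its mean signals were 22.1 ± 3.1 and 24.2 ± 5.5 for FLANC shRNA and 18.2 ± 4.3 and 20.2 ± 6.3 for control (SD over spots, arrays 1 and 2).

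All 21 ATF4-list genes were lower in the FLANC shRNA channel on both arrays. A dye or hybridisation bias of single probes as the cause of this direction is argued against by the 10 of these genes that had a second probe. The median of the second probes was -0.891 and 10 of 10 were below 0. Sizes differed by probe: SLC7A1 read -1.278 by the brightest and -0.2233 by the second probe, and SLC3A2 -1.225 and -1.476. Both genes were chosen after their values were seen. An exchange of the dyes in the labels, which would turn every direction, cannot be told apart from the labelled orientation, since 0 probes were named for FLANC. A dye effect shared by all probes of these genes was not testable either, as no array had the dyes swapped. The difference between shRNA and control, the one the design names, stays open beside these. It includes any effect of the hairpin other than on FLANC, since only 1 hairpin was used and the titles name an empty vector as control.

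Metallothionein ratios were opposite on the 2 arrays. Different control RNA on the 2 arrays is argued against for these genes only. The control channel differed by a median of -0.195 over the list (array 1 minus array 2, log2), and the FLANC shRNA channel by 1.83. Whether the probes of near-identical metallothionein genes read a single transcript stays open: SLC30A1, which has no such similarity, also differed in the FLANC shRNA channel, by 1.04, but a single gene excludes nothing. No biological explanation was tested, since the design gives no difference between the FLANC shRNA cultures. A candidate for follow-up is therefore a difference in zinc or other metal exposure between these cultures, which may apply but was not measured.

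Ratios were wider on array 1 than on array 2. One common compression of array 2 was not settled as a cause. The distance of array 2 from a common factor times array 1 differed between the 12 passing lists for each factor tried. Factors ran from 0 to 1.5 in steps of 0.05 (largest permutation p = 1e-04, the smallest that 10000 resamples can give). But the permutation treats genes as independent, and genes of a list may shift together between the arrays. The 12 lists had also passed on the mean of the same arrays. The medians of arrays 1 and 2 were 0.57 and 0.56 for cholesterol synthesis, -0.76 and -0.25 for ribosomal proteins and 1.06 and 0.47 for heat shock. Spot noise, in Cy3 or either channel, was not settled as a cause. It is independent between genes, and by means over genes all 12 lists were wider on array 1 (mean over 256 genes 0.33, SD 0.58, permutation of signs p = 1e-05). By medians DNA replication was not wider, at 0.35 and 0.38. But these lists had passed on the mean of the same arrays, so part of that width may come from their choice. The SD between replicate spots was 0.978 in Cy3 relative to Cy5, which compares channels and not arrays. This SD was larger on array 1 than on array 2 in both channels (Cy3 0.1885 and 0.1554, Cy5 0.1993 and 0.1505). No biological explanation was tested, and unequal knock-down on the 2 arrays stays open because no probe carried the name FLANC.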

How the results depend on the processing

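The alternatives were fixed before the data were examined, except the list test used with trend and robust moderation, which replaced camera with its own variance trend after that test had lost 3 lists. No separate paired analysis was run, because each ratio already sets FLANC shRNA against the control on the same array. Of the 12 lists that passed, 11 kept direction and side of the threshold under all 14 settings of signal, filter, probe, moderation and threshold. Of these settings, leaving out saturated spots (there were none), trend and robust moderation and the 0.1 threshold changed no ratio, and the deposited table repeats the scanner ratio. Aquantile adjusts brightness and leaves the ratio of each spot unchanged, so it could alter only which probe was kept for a gene. It gave 2836 genes at an unadjusted limma p under 0.05 against 2837 and is no separate check of the ratios. The exception among the 12 lists was the STAT3 list with the scanner ratio or deposited table, and the NF-kB list passed only with every probe counted (camera adjusted p = 0.0466). With camera's own variance trend counted too, 8 held and 9 passed, as the p53, unfolded protein response and Wnt lists were lost. The count of passing lists fell to 0 with an estimated correlation and to 1 with fry, on 1 residual degree of freedom. The count of passing genes, 0 in all other settings, was 27 with plain subtraction and 26 with trend and robust moderation. Genes at least 2-fold higher on both arrays numbered 38 with plain subtraction, 17 with offset 16, 79 with the scanner ratio and the deposited table, 16 with every probe counted (more features tested) and 194 at 1.5-fold. The lower ones numbered 181, 252 with the scanner ratio and the deposited table, and 436 at 1.5-fold. With either array left out the higher genes ranged from 23 to 483 and the lower from 143 to 842, as a single array sets no second condition. The share of genes with the same sign was 61.5% with median centring, 63.1% with the scanner ratio and the deposited table and 59.2% without a filter on dim probes. The cause was not tested except where stated. The 24 named genes, VEGFA and STAT3 kept their sign in all 416 values under the alternatives. These values include the settings that change no ratio, and Aquantile, which changes no spot ratio. The 24 had also been chosen for the same sign on both arrays, so leaving out an array could not turn their sign. By the mean of probes SLC7A11 was at -1.58, VEGFA at -1.18, NIBAN1 at -1.98 and GRIN2C at 0.68. With the scanner ratio STAT3 was at 0.47. With 1 array left the limma and set tests have no residual degrees of freedom and were not run. Signal over background limits low genes, whose ratios the offset of 50 shrinks.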

Other observations

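Gene families were also taken by symbol, after the lists had been seen, and the ribosomal and proteasome families kept their sign on both arrays under the 7 other background and scaling settings. Of these settings, Aquantile gave the same medians as the main one, and the deposited table repeats the scanner ratio. Mitochondrial ribosomal proteins had medians of 0.53 and 0.14 over 77 genes, with 55 higher and 7 lower on both arrays (camera adjusted p = 1.91e-10, 0.492 with an estimated correlation). Proteasome subunits had medians of 0.50 and 0.11 over 44 genes, with 28 higher and 0 lower (camera adjusted p = 2.14e-09, 0.492 with an estimated correlation). Over 76 cytosolic ribosomal proteins the medians were -0.72 and -0.22, with 67 lower and 2 higher, and -0.31 and -0.10 with the scanner software's ratios (camera adjusted p = 1.67e-16, 0.492 with an estimated correlation). This family overlaps the fixed list of 30 ribosomal genes on the same arrays, so its test is not separate support. Chaperonin subunits, the last of the 4 families tested, had medians of 0.53 and -0.02 over 10 genes, with 4 higher and 1 lower (camera adjusted p = 0.0129, 0.492 with an estimated correlation). The medians of the cytosolic and the mitochondrial ribosomal families lay on opposite sides of 0 on both arrays, and the difference between the families was not tested.

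Amino acid transporters outside the lists did not move as one family, with 9 of 17 lower and 4 higher on both arrays and a median of -0.07. The lowest, named after their values were seen, were SLC43A1 (-1.75 ± 0.50), the glutamine carrier SLC38A1 (-1.19 ± 0.12) and the neutral amino acid carrier SLC1A4 (-1.17 ± 0.66), and the highest was SLC7A6 (0.84 ± 0.71).

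A hypothesis was tested on a second group, chosen after its values were seen. If the amino acid response was lower in FLANC shRNA cells, cytosolic aminoacyl-tRNA synthetases outside the ATF4 list may be lower than mitochondrial ones. The 14 cytosolic enzymes had a mean of -0.36 ± 0.45 and the 15 mitochondrial ones 0.16 ± 0.26 (SD over genes), a difference of -0.52 (two-sided permutation test, p = 0.00067). On both arrays 10 of the 14 were lower and 1 higher, and 2 of the 15 were lower and 7 higher. The values are consistent with the hypothesis, but mitochondrial ribosomal proteins and oxidative phosphorylation subunits were higher too, so part of the difference may come from the mitochondrial side. Genes within a pathway are not independent, KARS1 and GARS1 serve both compartments, and the same arrays gave the hypothesis and the test.

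Across all genes, 5 had ratios of at least 2-fold in opposite directions on the 2 arrays, among them MT1E, MT1M, IGF1R and RGCC, which are named after their values were seen.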
